A study of Mus musculus with 75 samples.

How the data were processed

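The series holds 75 RNA-seq libraries of mouse epididymal white fat (eWAT), inguinal white fat (iWAT) and gastrocnemius muscle. Per the labels, the animals carry 1 of 4 combinations of nuclear (n) and mitochondrial (mt) genome: the wild types C57n:C57mt and C3Hn:C3Hmt, and the mitochondrial-nuclear exchange lines C57n:C3Hmt and C3Hn:C57mt. Per the labels, they were fed chow or, from week 6 to week 12 to 13 of age, a high-fat diet (HFD). The 47 chow libraries cover all 3 tissues and the 28 HFD libraries both fat depots, which makes 20 groups of 3 or 4 libraries. The groups of 3 are C3Hn:C3Hmt on chow and both exchange lines on HFD in eWAT, and both C3Hn lines on HFD in iWAT. Replicates of a group carry different animal numbers in the titles and were treated as separate animals, and 20 animals gave both fat depots. Sex is not stated in the labels.

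Per the submitters' processing notes, reads were counted with RSEM against genome build mm9, and DESeq2 1.10.1 was used for testing. The RSEM version, the annotation release and the read mapper are not given in the sources used here. The deposited gene tables and transcript tables hold RSEM expected counts, not normalized, with 1 column per library; 68.4% of the chow values and 69.3% of the HFD values are whole numbers. The chow file has 22423 genes and the HFD file 21983 genes, with 21625 in both. Of the deposited quality tables of the sequencing provider, the following were read, in the units that the file headers name. Per the file headers, G+C content of aligned reads, duplicate reads, spike-in reads, ribosomal reads and reads mapped to the transcriptome are in percent. Per the file headers, the rate of bases that differ from the reference is a fraction of aligned bases. Per the file headers, the other quantities are mean insert length in bases, the number of genes detected and read clusters in M. The software behind these tables is not stated. The deposited normalized tables are the counts of each library divided by 1 factor, rescaled, and were not used, because the counts they came from are deposited.

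Total expected counts were 24.8 ± 2.84 M counts (M, mega) per library (mean ± SD) in eWAT on chow, 18.7 ± 2.29 M in eWAT on HFD, 23.2 ± 1.6 M in iWAT on chow, 19.0 ± 2.75 M in iWAT on HFD and 24.1 ± 2.75 M in muscle, with the smallest library at 15.8 M. All chow libraries come from 1 sequencing run and all HFD libraries from the other 3, by the titles, so no model separates diet from run. A run covariate adjusts only between HFD runs. On chow the nuclear genome follows the lane in the titles apart from 1 eWAT library, while both mitochondrial genomes of a nuclear background share run and lane. The labels do not explain the run and lane codes.

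Expected counts were rounded and each tissue was fitted once over all its groups with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test, TMM normalization). Genes were kept by filterByExpr with a minimum count of 10, a minimum total of 15 and a minimum proportion of 70%, which left 17781 genes in eWAT, 16888 in iWAT, 13735 in muscle and 18423 in the joint fit of both depots. A gene is called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Adjusted p values are from edgeR unless another tool is named, and all tests are two-sided. The 28 comparisons are HFD minus chow as the mean of 4 genotypes and in each genotype; the difference of this response between the mitochondrial genomes of a nuclear background (diet by mtDNA interaction); exchange line minus wild type on each diet; C57n minus C3Hn on chow, averaged over both mitochondrial genomes; and the eWAT response minus the iWAT response (depot by diet interaction). The diet by nuclear genome interaction of each depot was added after the data were seen. Log2 fold changes are given with their standard error (SE), the groups with mean and SD in counts per M (CPM), and n is the number of libraries, each from 1 animal. Errors and floors cover what the libraries and counts of these animals show; a floor of 3 counts per library covers counting error only.

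The size of the diet response was compared between mitochondrial genomes directly: the variance over genes of the difference in mean log2 CPM (prior count 2), less the value expected from the spread within groups, as a square root. Mitochondrial labels were permuted within each diet in an exact test. The 34 gene lists were written before the data were examined, as were the comparisons, the tests, the alternatives named below as chosen beforehand and the rule for genes named. The lists cover de novo lipogenesis, cholesterol synthesis, triglyceride storage, lipolysis, fatty acid oxidation, nuclear OXPHOS subunits, mtDNA-encoded genes, mitochondrial ribosome, TCA cycle, mtDNA maintenance and biogenesis, brown and beige fat, adipokines and fat expansion, adipocyte identity, insulin signalling, macrophage, lymphocyte and lymph node, granulocyte and mast cell, extracellular matrix, endothelial, mesothelial, epididymis, keratinocyte and mammary epithelium, fast muscle, slow muscle, erythroid, circadian clock, immediate early and heat shock, integrated and mitochondrial stress response, antioxidant, interferon response, MHC class II, cell cycle, cytosolic ribosome and histone genes. Lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and again with the correlation estimated from the residuals, and adjusted over the lists of a comparison. Camera compares a list with all other genes. Members called were counted over all genes tested and adjusted over the list alone.

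Named genes follow a rule. Gene models without a gene-style name were passed over, and a mean log2 CPM of at least 1 was required. For the mean diet comparison of a depot these are the 8 called genes with the largest rise and the 8 with the largest fall. For the depot and nuclear comparisons they are the 4 called genes with the smallest p in each direction. For mitochondrial comparisons and interactions they are the same 4, or the 1 gene with the smallest p in each direction where none is called. For a list they are up to 4 members with the smallest p. Lep, Adipoq, Ucp1, Nnt, H2-Ea, Xist, Ddx3y and mt-Nd4 were always looked up; Xist is absent from the tables. Hmgcs1, Ighm, Ly6g and the mtDNA-encoded genes other than mt-Nd4 were not found in the tables under the names searched, and the mtDNA-encoded list was therefore not tested. Cox2 and Atpase6, found after the data were seen, were read as mt-Co2 and mt-Atp6 by name, without a position, and their GC correction used those sequences. In eWAT their means were 13.10 and 13.36 log2 CPM, with mt-Nd4 at 12.96 and Ptgs2, which shares the synonym Cox2, at 4.64. Gene models without a gene-style name were not searched for mtDNA-encoded genes. Me1, Nampt, Lyz2, Lyz1, Epcam, Bhlhe40, Bhlhe41, Cxcr5, Hsph1, Irgm1 and Rplp0 stand in the tables only under the older symbols Mod1, Pbef1, Lyzs, Lyz, Tacstd1, Bhlhb2, Bhlhb3, Blr1, Hsp110, Irgm and Arbp, which were matched by transcript after the data were seen. The lists were tested without these 11 genes, and again with them. Genes named outside the rule are marked as chosen after their values were seen.

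The pipeline was first run on simulated negative binomial counts with means, library sizes and dispersion trend of each tissue and 200 changed genes. Such counts lack neighbouring tissue, so real shares may differ. For the mean diet comparison in eWAT, 22.4% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 98.5% of those changed 4-fold were called, and 2.4% of calls were false; DESeq2 1.42.0 gave 21% false calls on the same simulated counts. For 1 genotype in eWAT the shares called were 0%, 4.5% and 75.8%, for the eWAT diet by mtDNA interaction 0%, 4.5% and 22.7%, for the eWAT mtDNA comparison on HFD 0%, 6% and 54.5%, for the nuclear comparison in eWAT 4.5%, 22.4% and 83.3%, and for the mtDNA comparison in muscle 82.1%, 95.5% and 100%. In iWAT the mean diet comparison called 28.4%, 77.6% and 100%, 1 genotype 3%, 7.5% and 71.2%, the interaction 0%, 3% and 43.9%, the mtDNA comparison on HFD 1.5%, 22.4% and 86.4%, and the nuclear comparison 7.5%, 50.7% and 98.5%. For the depot by diet interaction the shares were 4.5%, 56.7% and 89.4%. Camera gave a changed list a p of 5.6e-61 (4.2e-14 with an estimated correlation) and 3 of 100 random lists a p under 0.05 either way. The exact permutation test of response size gave p = 0.0371 for a simulated SD of 0.5 (estimate 0.392) and p = 0.693 for none. With a simulated trend on GC content in the HFD libraries, 69.4% of calls were false before and 3.4% after the trend was removed.

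The alternatives chosen beforehand were RLE size factors, no expression filter, DESeq2, counts thinned to the smallest library, the HFD sequencing run as a covariate, only the groups of a comparison in the fit, 3 libraries per group (mean of 10 draws), limma-voom with and without the animal as a block for the depot interaction, a minimum mean of 10 CPM and trimming 2% of genes at each end for response size, an estimated correlation for the lists, and leaving out each library in turn. Chosen after the data were seen were a fit without the 6 eWAT libraries in which the mean log2 CPM of the keratinocyte and mammary epithelium list is above 0, a fit without 5 of these that keeps C3Hn:C3Hmt HFD replicate 1, a fit of iWAT with the lymphocyte and fast muscle list means as covariates, the lists with the 11 genes under older symbols added, and the removal of each library's trend on gene GC content and length, for the mean diet responses also on each alone. That trend was a spline with 5 degrees of freedom, fitted to genes with a match in the mm9 annotation (NCBIM37, GENCODE vM1; 15240 by name and 2436 by another name of 22781), and the results were tested as before. Other splits of the libraries into groups of the same sizes were fitted for each comparison (all splits up to 35, otherwise 30 with the real one). The nuclear genome of each library was checked, after the data were seen, with genes called and changed over 2-fold between the nuclear genomes on chow in all 3 tissues (mean log2 CPM of genes higher in C57n minus that of genes lower). Correlations across libraries have permutation p values from 100000 permutations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Nothing was left out among the libraries, and no column of the count tables belongs to no sample.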

Results

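Adipose tissue of mice with exchanged mitochondrial and nuclear genomes was profiled on chow and on a high-fat diet (HFD) in the epididymal (eWAT, 29 libraries) and inguinal (iWAT, 30 libraries) depots, with gastrocnemius muscle on chow (16 libraries). Between diets, macrophage, matrix, lipogenic and thermogenic genes were called in both depots. Between nuclear genomes genes were called in all 3 tissues, with other groupings of the libraries giving more calls in eWAT. Between origins of the mitochondrial DNA (mtDNA) 3 genes were called over 10 comparisons, each call being lost without single libraries, and 0 genes were called for its interaction with diet in each of 4 tests (DESeq2 7 to 387). All HFD libraries were sequenced in other runs than the chow libraries and differ from them in G+C content (GC), so for diet each gene below was also tested after each library's trend on GC content and length was removed (GC-corrected, chosen after the data were seen).

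In eWAT, HFD minus chow as the mean of 4 genotypes (15 chow and 14 HFD libraries) called 7294 of 17781 genes, 3263 higher and 4031 lower, and 2050 of them changed at least 2-fold. Mmp12, which encodes macrophage elastase, rose by 2.99 ± 0.51 log2 units (± SE; adjusted p = 0.000105). The serpin Serpinb9b rose by 3.25 ± 0.50 (3.23e-05), the retinol dehydrogenase Dhrs9 by 2.97 ± 0.45 (2.78e-05), Il1rn, the interleukin-1 receptor antagonist, by 2.44 ± 0.44 (0.000181), and the C-type lectin Clec4d by 2.40 ± 0.50 (0.000688). Tph2, known for neuronal serotonin synthesis, rose by 2.79 ± 0.55 (0.000468) and the ubiquitin-like Ubd by 2.41 ± 0.50 (0.000758). Itgad, an integrin of macrophages, rose by 2.53 ± 0.62 (0.00292), and lost its call without C57n:C3Hmt HFD replicate 3 (1.58, 0.0588) and with run as a covariate (0.0686). Mmp12 lies on chromosome 9 at 7344381 to 7369499 (NCBIM37, the same assembly as mm9, with GENCODE vM1).

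The leptin gene Lep rose in eWAT by 1.03 ± 0.34 log2 units (adjusted p = 0.0207, GC-corrected 0.99, 0.0539; 0.114 with run as a covariate). Adiponectin, Adipoq, was not called (-0.25 ± 0.30, 0.529), but without 6 eWAT libraries that carry epithelial RNA it was called lower (-0.64, 0.00416). The Y-linked Ddx3y rose by 1.46 ± 0.19 (3.88e-06, GC-corrected 0.94, 0.00125). Nnt, the mitochondrial transhydrogenase, was called lower only after GC correction (-0.20 ± 0.11, 0.144, corrected -0.28, 0.0391), and the mtDNA-encoded mt-Nd4 was not called (-0.17 ± 0.17, 0.433). Cox2 and Atpase6, by name mtDNA-encoded and looked up after the data were seen, were lower (-0.62 ± 0.14, 0.00178, GC-corrected -0.71, 0.0174, and -0.42 ± 0.17, 0.0485, GC-corrected 0.0827). Neither was called with run as a covariate (0.0877 and 0.452). Cox2 was called in all 29 fits without 1 library and Atpase6 in 7.

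The 8 genes with the largest fall in eWAT were Cuzd1, Ptgds, Tacstd1, Actg2, Prom1, Krt18, Spink2 and Gstm7, which include genes of secretory epithelium and smooth muscle. Krt18, a keratin of simple epithelia, fell by 3.06 ± 0.88 log2 units (adjusted p = 0.00875) and by 0.30 without the 6 libraries (0.65). Without these libraries 7 of the 8 lost their call (Ptgds -4.46 ± 1.38, 0.0133, then -1.02, 0.221), and only Gstm7, a glutathione transferase, stayed (-3.01 ± 0.78, 0.00423, then -1.09, 0.0046). With run as a covariate Ptgds (0.276), Krt18 (0.112) and Gstm7 (0.0943) were not called. The thermogenic uncoupler Ucp1 fell by 4.15 ± 1.30 (0.0143), by 1.40 without the 6 libraries (0.258) and by 2.06 without C57n:C3Hmt chow replicate 1 (0.0678).

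**Figure D1:**
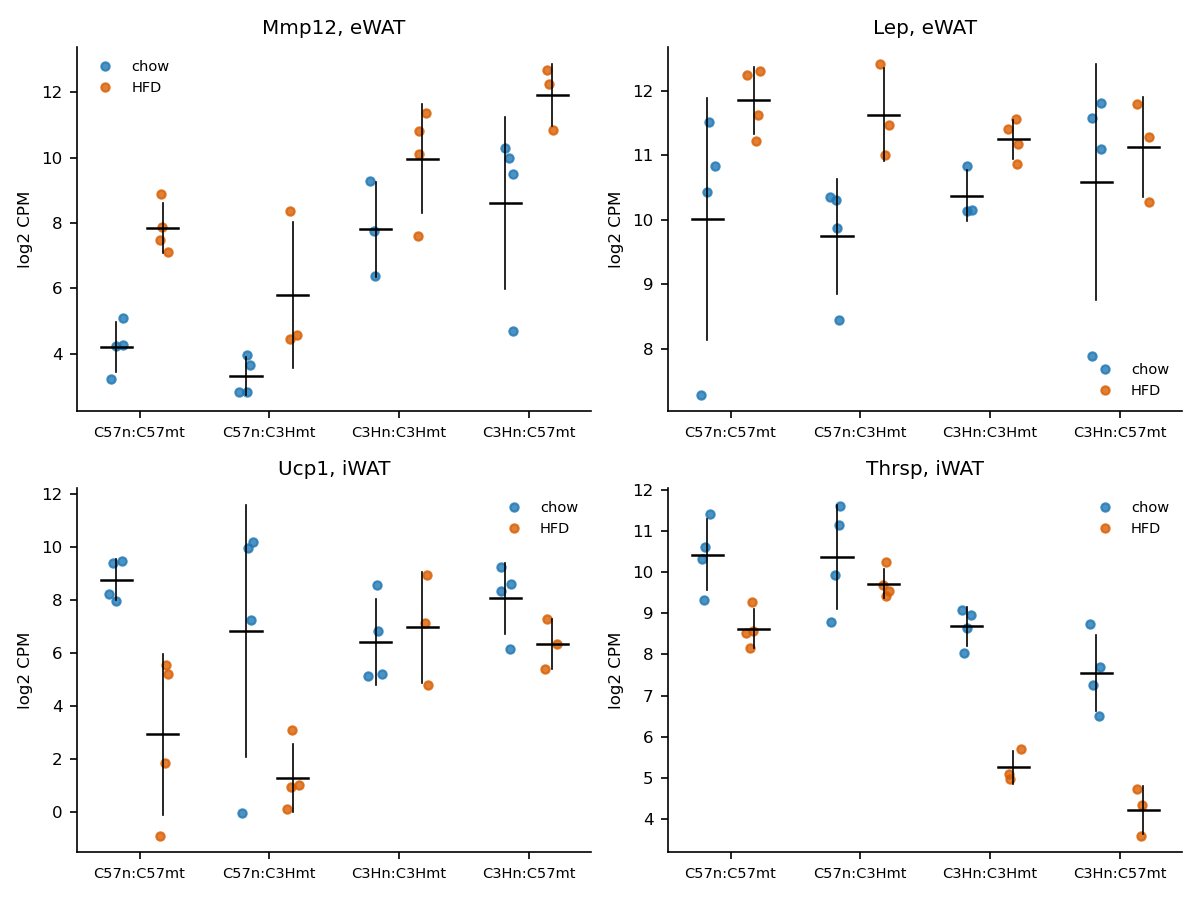
Expression (y axis, log2 CPM) of Mmp12 and Lep in eWAT and of Ucp1 and Thrsp in iWAT by genotype (x axis), on chow (blue) and HFD (orange); points are libraries, horizontal lines group means and vertical lines 1 SD. Mmp12 rises by a mean of 2.99 and Thrsp falls by a mean of 2.46 log2 units.

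Of 28 macrophage genes measured in eWAT, 21 rose and 0 fell (21 adjusted over the list alone, median 1.39 log2 units, camera adjusted p = 1.26e-09, 0.897 with an estimated correlation). The chemokine receptor Ccr2 rose by 1.74 ± 0.28 (4.95e-05), Mpeg1, a pore-forming protein of phagocytes, by 1.81 ± 0.31 (0.000111), and Cd84 by 2.10 ± 0.35 (9.68e-05). Of 30 extracellular matrix genes 20 rose and 0 fell (23 adjusted over the list alone, 0.78, camera adjusted p = 4.32e-10, 0.897 with an estimated correlation). Collagen cross-linking Lox rose by 1.58 ± 0.20 (3.99e-06), periostin (Postn) by 1.29 ± 0.18 (1.26e-05) and Col1a2 by 0.82 ± 0.15 (0.000202). Of 24 cell cycle genes 13 rose and 0 fell (14 adjusted over the list alone, 0.65, camera adjusted p = 1e-05, 0.897 with an estimated correlation), with cyclin Ccna2 at 1.08 ± 0.22 (0.000697) and the proliferation marker Mki67 at 0.96 ± 0.22 (0.00184, GC-corrected 0.0629). After GC correction 22 macrophage, 22 matrix and 9 cell cycle genes rose.

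Of 19 de novo lipogenesis genes in eWAT 13 fell and 0 rose (14 adjusted over the list alone, median -0.77 log2 units, camera adjusted p = 0.00379, 0.897 with an estimated correlation), and 8 fell after GC correction. The lipogenic regulator Thrsp fell by 1.99 ± 0.36 (0.000206), ATP citrate lyase Acly by 0.93 ± 0.19 (0.000534) and Srebf1 by 0.77 ± 0.17 (0.00138). Of 73 nuclear OXPHOS genes 47 fell (50 adjusted over the list alone, -0.36, camera adjusted p = 1.12e-10, 0.897 with an estimated correlation), but only 4 after GC correction (camera p = 0.155). The complex I gene Ndufs7 fell by 0.73 ± 0.10 (1.38e-05, corrected -0.19, 0.393) and Cox4i1 of complex IV by 0.73 ± 0.12 (5.58e-05, corrected -0.17, 0.458). Of 75 mitochondrial ribosome genes 39 fell (44 adjusted over the list alone, -0.28, camera adjusted p = 2.04e-08, 0.897 with an estimated correlation), 9 of them after correction, with Mrps34 at -0.62 ± 0.09 (1.28e-05, corrected -0.16, 0.257). Of 78 cytosolic ribosome genes, which share reads with near-identical copies and are uncertain, 31 fell (27 adjusted over the list alone, -0.34, camera adjusted p = 3.98e-07, 0.897 with an estimated correlation), with Rpl28 at -0.67 ± 0.14 (corrected 0.03, 0.912).

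Other eWAT lists did not pass the camera test apart from epididymis genes, and their called members are given as higher and lower counts. Brown and beige fat genes (17 measured) had 1 and 7, with the lipid droplet gene Cidea at -2.23 ± 0.46 (0.000688) and Tmem26, a beige marker, at 2.34 ± 0.45 (0.000382). Adipocyte identity (18) had 1 and 6, with adipsin (Cfd) at -1.87 ± 0.33 (0.00013), Klf15 at -0.92 ± 0.16 (0.000126) and the beta-3 adrenergic receptor Adrb3 at -1.37 ± 0.30 (0.0013); after GC correction the counts were 0 and 4, and without the 6 libraries 1 and 15. Cholesterol synthesis (22) had 4 and 6 (Hsd17b7 0.72 ± 0.09, 3.66e-06, corrected 0.43; Stard4 0.99 ± 0.19, 0.000285), with a median of 0.01 and a mean of -0.05. Fatty acid oxidation (23) had 1 and 8, lipolysis (12) 0 and 2, triglyceride storage (19) 0 and 1, TCA cycle (18) 0 and 4, and mtDNA maintenance (20) 2 and 8 (Gabpa 0.65 ± 0.07, 4.87e-07, corrected 0.26). Adipokines (17) had 3 and 3, and insulin signalling (20) 6 and 3 (Pdk1 -0.48 ± 0.12, 0.00329).

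Immune lists in eWAT counted 0 higher and 8 lower of 25 lymphocyte genes (T-cell receptor Cd3e -1.33 ± 0.28, 0.000902), 2 and 0 of 13 granulocyte genes (S100a8 1.33 ± 0.41, 0.0125, with run as a covariate 0.0555), 1 and 1 of 26 interferon genes, and 2 and 0 of 10 MHC class II genes (their activator Ciita 0.92 ± 0.24, 0.00398). Stress lists counted 4 and 8 of 28 antioxidant genes (heme oxygenase Hmox1 1.24 ± 0.27, 0.0011; Gsta4 -1.75 ± 0.31, 0.000155), 1 and 6 of 24 stress response genes (the mitochondrial protease Clpp -0.80 ± 0.09, 9.17e-07, GC-corrected -0.39) and 5 and 3 of 21 immediate early and heat shock genes (Fos 0.81 ± 0.17, 0.000695). Clock genes (17) had 1 and 7, with Clock at 0.93 ± 0.14 (3.73e-05, GC-corrected 0.43). Endothelial genes (18) had 0 and 1, erythroid genes (7) 0 and 0 and histone genes (24, uncertain because of shared reads) 0 and 3. Lists of neighbouring tissue had 3 higher and 4 lower of 10 mesothelial genes, 0 and 7 of 11 keratinocyte and mammary genes, 2 and 7 of 19 fast muscle genes (the glycolytic Eno3 -1.25 ± 0.27, 0.000875, without the 6 libraries -0.69), and 1 and 3 of 6 slow muscle genes. Of 20 epididymis genes 3 fell (Crisp1 -9.98 ± 2.58, 0.00554, uncertain in size with 0 counts in all C57n HFD libraries, not called with run as a covariate, -6.31 without the 6 libraries; median of the list -4.49, camera adjusted p = 0.0202, 0.897 with an estimated correlation).

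Within genotypes, the eWAT response called 3003 genes in C57n:C57mt (1190 higher, 1813 lower), 1241 in C57n:C3Hmt (562, 679), 296 in C3Hn:C3Hmt (156, 140) and 1982 in C3Hn:C57mt (1031, 951). After GC correction these were 1190, 0, 2 and 210. The median absolute change of the genes that lost their call went from 0.84, 0.96, 0.72 and 0.89 log2 units to 0.56, 0.70, 0.49 and 0.49. C57n:C3Hmt had 50 without its HFD replicate 1, and C3Hn:C3Hmt had 5 without its chow replicate 3 and 2177 without the 5 other libraries with epithelial RNA. Mmp12 rose in C57n:C57mt from 20.3 ± 10.2 CPM (mean ± SD, n = 4) to 257 ± 150 CPM (n = 4; 3.66 log2 units, adjusted p = 0.0169). That call was lost without its chow replicate 3 or HFD replicate 4 (highest 0.0739). In C57n:C3Hmt it rose by 3.56 ± 1.02 (0.0403, GC-corrected 0.101), but the call was lost without any of the 3 HFD libraries or chow replicates 1, 2 or 4, with a lowest value of 1.10 and a highest p of 0.502. Mmp12 was not called in C3Hn:C3Hmt (308 ± 281 to 1431 ± 1040 CPM, n = 3 and 4, 0.277) or C3Hn:C57mt (2.54 ± 0.98, 0.0913). Lep was called in none of the 4 genotypes (lowest adjusted p = 0.0922). Genes called in both C57n lines were 382 higher and 227 lower (37.6 and 69.2 if independent), and in both C3Hn lines 137 and 113 (9.05 and 7.49).

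In iWAT the mean diet comparison (16 chow and 14 HFD libraries) called 6345 of 16888 genes (3615 higher and 2730 lower). Ucp1 fell by 3.30 ± 0.71 log2 units (adjusted p = 0.000783), Cidea by 2.35 ± 0.36 (1.81e-05) and the thermogenic thioesterase Acot11 by 3.43 ± 0.53 (2.02e-05). The fatty acid elongases Elovl6 and Elovl3 fell by 3.03 ± 0.51 (6.23e-05) and 2.82 ± 0.58 (0.000511), and Thrsp by 2.46 ± 0.28 (2.99e-07). Sorcs2 fell by 2.42 ± 0.42 (9.04e-05), and the largest fall was that of the gene FAE (-5.31 ± 1.17, 0.00113), which had 0 counts in all 3 C3Hn:C57mt HFD libraries, so its size is uncertain. All 8 stayed called after GC correction and without any 1 library.

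The imprinted zinc finger gene Peg3 rose in iWAT by 2.24 ± 0.49 log2 units (adjusted p = 0.000957), Pra1 by 2.30 ± 0.54 (0.00177) and Lmbrd2 by 1.73 ± 0.25 (1.1e-05). Slc5a7, the choline transporter, rose (0.0117, GC-corrected 0.0779), and Mup1, whose reads are shared with near-identical copies and which is uncertain, by 2.84 ± 0.82 (0.00824). Calls of Itgad (2.23 ± 0.77, 0.0252) and Serpina3k (2.15 ± 0.71, 0.0203) were lost without C3Hn:C3Hmt HFD replicate 2 (Itgad 1.45 and 0.14, Serpina3k 1.38 and 0.119), and that of Tph2 (1.75 ± 0.58, 0.0202) without C57n:C3Hmt HFD replicate 4 (0.0723). All 3 lost their call with run as a covariate (0.561, 0.155 and 0.267). Lep rose by 1.04 ± 0.33 (0.016, GC-corrected 0.0544; without C3Hn:C3Hmt HFD replicate 2 0.0583). Ddx3y rose by 1.25 ± 0.26 (0.000533, GC-corrected 0.68, 0.0568). Adipoq (0.16 ± 0.17, 0.485) and Nnt (0.27 ± 0.11, 0.0548) were not called, and mt-Nd4 was lower only after GC correction (-0.05 ± 0.15, 0.806, corrected -0.51, 0.0376). Cox2 was lower (-0.64 ± 0.17, 0.0042, GC-corrected -0.95, 0.000527, with run as a covariate 0.0948) and Atpase6 only after GC correction (-0.35 ± 0.16, 0.0828, corrected -0.74, 0.00384).

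Of 19 lipogenesis genes in iWAT 15 fell and 0 rose (15 adjusted over the list alone, median -0.90 log2 units, camera adjusted p = 8.89e-07, 0.892 with an estimated correlation), and 12 fell after GC correction. Acly fell by 1.85 ± 0.29 (2.48e-05) and Acaca, acetyl-CoA carboxylase, by 1.74 ± 0.28 (2.7e-05). Of 17 brown and beige genes 9 fell and 0 rose (9 adjusted over the list alone, -0.97, camera adjusted p = 0.0057, 0.892 with an estimated correlation), among them Cox8b (-1.74 ± 0.26, 1.47e-05). The lymphocyte list mean was 3.72 log2 CPM on chow and 1.85 on HFD. With lymphocyte and fast muscle means as covariates 7 brown and beige genes fell, with Ucp1 at -2.58 (0.0257), Cidea at -2.04 (0.000288) and Acot11 at -2.39 (0.00171). Of 23 fatty acid oxidation genes 10 fell and 1 rose (10 and 1 adjusted over the list alone, -0.30, camera adjusted p = 0.0057, 0.892 with an estimated correlation), with Acadvl lower (0.000329). Of 18 TCA cycle genes 9 fell (10 adjusted over the list alone, -0.32, camera adjusted p = 0.009, 0.892 with an estimated correlation; 5 after GC correction). Of 73 OXPHOS genes 42 fell (43 adjusted over the list alone, -0.32, camera adjusted p = 1.39e-09, 0.892 with an estimated correlation; 26 after GC correction), with Ndufa13 at -0.81 ± 0.11 (4.11e-06, corrected -0.33, 0.0153). Of 75 mitochondrial ribosome genes 28 fell (28 adjusted over the list alone, -0.19, camera adjusted p = 1.14e-05, 0.892 with an estimated correlation), with Mrpl38 at -0.64 ± 0.08 (1.38e-06, corrected 0.0616).

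Of 28 macrophage genes in iWAT 18 rose and 0 fell (20 adjusted over the list alone, median 0.58 log2 units, camera adjusted p = 5.17e-05, 0.892 with an estimated correlation), with Ccr2 at 1.29 ± 0.12 (2.51e-08, GC-corrected 0.82) and Emr1, the F4/80 antigen, at 0.87 ± 0.15 (7.14e-05). Of 30 matrix genes 13 rose (13 adjusted over the list alone, 0.43, camera adjusted p = 0.00119, 0.892 with an estimated correlation), with Postn at 0.88 ± 0.15 (5.33e-05) and fibrillin Fbn1 at 0.86 ± 0.20 (0.00144). Of 24 cell cycle genes 10 rose (10 adjusted over the list alone, 0.61, camera adjusted p = 0.0263, 0.892 with an estimated correlation; 2 after GC correction), with the kinase Cdc2a at 0.95 ± 0.19 (0.00039). Lymphocyte genes counted 0 higher and 0 lower of 26, with a median of -1.17 (camera adjusted p = 0.00547, 0.892 with an estimated correlation). Of 79 cytosolic ribosome genes 2 fell (0 adjusted over the list alone, camera adjusted p = 0.000491, 0.892 with an estimated correlation) and of 27 histone genes 7 (6 adjusted over the list alone, camera adjusted p = 0.00832, 0.892 with an estimated correlation); for these 2 lists reads are shared and the values uncertain.

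Remaining iWAT lists did not pass the camera test; higher and lower members were 3 and 7 of 21 for cholesterol synthesis, 1 and 3 of 19 for triglyceride storage, 1 and 5 of 12 for lipolysis (triglyceride lipase Pnpla2 -0.63 ± 0.14, 0.00103, GC-corrected 0.188), and 4 and 9 of 20 for mtDNA maintenance (the mitochondrial RNA polymerase Polrmt -0.75 ± 0.07, 2.25e-08, corrected -0.30). They were 5 and 1 of 17 for adipokines, 2 and 7 of 18 for adipocyte identity (Adrb3 -1.35 ± 0.26, 0.000226; Cfd -1.09 ± 0.19, 9.07e-05, corrected -0.66) and 6 and 2 of 20 for insulin signalling. Akt1 of that list turned direction with the correction (-0.19 ± 0.04, 0.00049, corrected 0.26, 0.000626). Granulocyte genes had 5 and 1 of 14 (S100a8 at 0.00193), endothelial 3 and 2 of 18, interferon 2 and 4 of 26, MHC class II 0 and 0 of 10, and erythroid, with shared reads, 0 and 3 of 7. Mesothelial genes had 0 and 0 of 5, keratinocyte and mammary 0 and 2 of 10 (Elf5 -1.17 ± 0.23, 0.000324), fast muscle 0 and 0 of 20 and slow muscle 2 and 0 of 14, with a median of -0.71. Clock genes had 1 and 3 of 17 (Clock 1.01, 8.37e-06, corrected 0.55), immediate early genes 2 and 2 of 21, stress response genes 2 and 4 of 24 (Clpp -0.68 ± 0.10, 8.32e-06, corrected -0.35) and antioxidant genes 3 and 6 of 28. Epididymis genes were not tested as a list in iWAT.

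**Figure D2:**
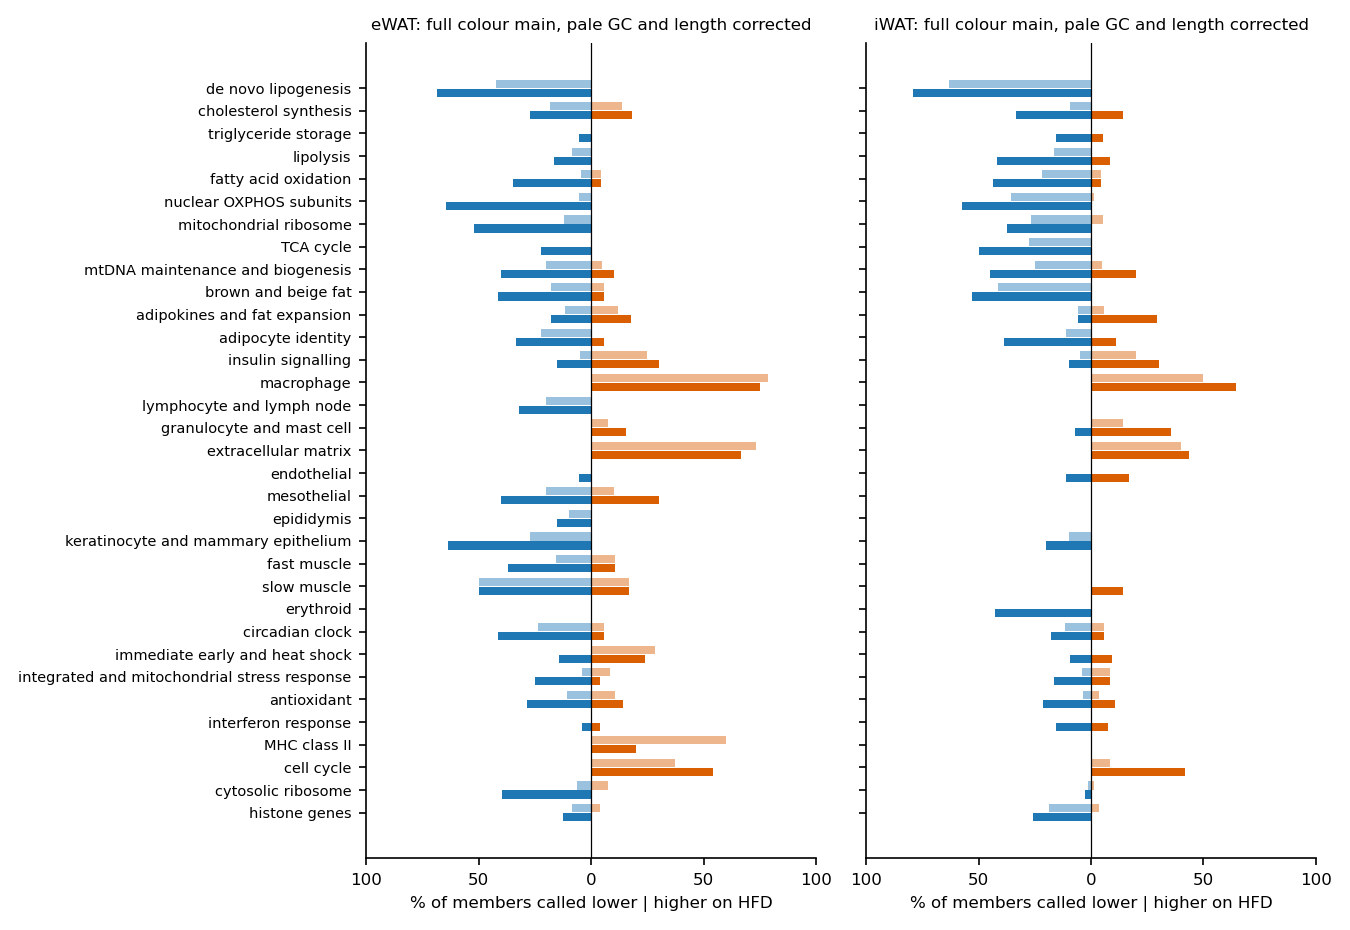
Percent of the measured members of each gene list (y axis) called lower (left) or higher (right) on HFD in eWAT and iWAT (x axis, percent); full colour is without and pale colour with GC correction. Macrophage genes called higher in eWAT are 21 of 28 before and 22 after correction, while nuclear OXPHOS genes go from 47 lower to 4.

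Within genotypes iWAT called 2812 genes in C57n:C57mt (1583 higher, 1229 lower), 2790 in C57n:C3Hmt (1630, 1160), 824 in C3Hn:C3Hmt (597, 227) and 1300 in C3Hn:C57mt (731, 569). After GC correction these were 466, 432, 6 and 26, and the median absolute change of the genes that lost their call went from 0.72, 0.69, 0.67 and 0.66 log2 units to 0.40, 0.37, 0.40 and 0.25. With only the groups of the comparison in the fit 0 were called in C57n:C3Hmt and 0 in C3Hn:C3Hmt. Ucp1 fell by 4.47 ± 1.40 log2 units in C57n:C57mt (adjusted p = 0.0309), a call lost after GC correction (0.0667) and without chow replicates 1 or 3 or HFD replicates 1, 3 or 4 (highest 0.0815). In C57n:C3Hmt it fell by 7.47 ± 1.61 (0.00314), and it was not called in C3Hn:C3Hmt (0.794) or C3Hn:C57mt (-1.89 ± 1.39, 0.448). Cidea fell by 3.49 ± 0.71 in C57n:C57mt (0.00247) and Acot11 by 5.20 ± 1.06 in C57n:C3Hmt (0.00188). Thrsp fell in C57n:C57mt (-1.92 ± 0.51, 0.0139, GC-corrected 0.0586, without chow replicate 3 0.0569), C3Hn:C3Hmt (-3.44 ± 0.61, 0.00287) and C3Hn:C57mt (-3.49 ± 0.61, 0.00133), but was not called in C57n:C3Hmt (-0.98 ± 0.50, 0.175). With only the groups of its own comparison in the fit, Ucp1 and Acot11 in C57n:C3Hmt (0.0711 and 0.0663) and Thrsp in C3Hn:C3Hmt (0.177) were not called. Both C57n lines shared 1037 higher and 733 lower genes (152.8 and 84.4 if independent), and both C3Hn lines 272 and 142 (25.8 and 7.65).

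Of 16372 genes tested in both depots, 2232 were higher on HFD in both and 1943 lower in both (710.9 and 611.8 if independent), with 7 and 13 in opposite directions. Both depots carry the same split of runs and the same direction of the GC trend, and after GC correction 826 were higher and 534 lower in both (204.7 and 116.4 if independent). The depot by diet interaction (59 libraries) called 8 of 18423 genes, 7 higher and 1 lower, with 2888 at unadjusted p under 0.05 (921.2 by chance) and 652 called by DESeq2. The fit takes libraries as independent although 20 animals gave both depots; limma-voom called 5 genes, and 31 with the animal as a block (consensus correlation 0.287). Dock8, a guanine nucleotide exchange factor of immune cells, rose more in eWAT by 1.42 ± 0.25 log2 units and Sbno2 by 0.80 ± 0.15 (each adjusted p = 0.0171, GC-corrected 0.1 and 0.106). Sbno2 lost its call in 6 of 59 fits without 1 library, such as eWAT C57n:C3Hmt chow replicate 1 (highest 0.0589). The scaffold gene Nbea was lower (-1.28 ± 0.27, 0.0492) and lost its call in 38 of 59 fits without 1 library, such as iWAT C3Hn:C3Hmt chow replicate 2 (highest 0.101). After GC correction 0 genes were called. The 8 genes had a median absolute log2 fold change of 1 before and 0.98 after, with a median SE of 0.2 and 0.23. Of 28 macrophage genes the median was 0.69 (8 called adjusted over the list alone, camera adjusted p = 5.68e-13, 0.921 with an estimated correlation), and of 30 matrix genes 0.41 (6 adjusted over the list alone, camera adjusted p = 6.97e-10, 0.921 with an estimated correlation). Lep (0.02) and Ucp1 (-0.84 log2 units, 0.893) were not called.

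No gene was called for a difference of the diet response between mitochondrial genomes in eWAT. In C57n 0 genes were called (1269 at unadjusted p under 0.05, 889.1 by chance; smallest adjusted p = 0.617; DESeq2 66), with the smallest p at the cytochrome Cyp4f39 (2.85 ± 0.63 log2 units) and the cargo receptor Lman1 (-0.86 ± 0.20). In C3Hn 0 were called (1247; 0.511; DESeq2 387), with P4ha1, a collagen hydroxylase, at 1.47 ± 0.41 and the epididymal peroxidase Gpx5 at -23.12 ± 6.12, a value of libraries near 0 counts and single libraries with epithelial RNA, which became -0.91 without the 6 libraries with epithelial RNA. In iWAT C57n 0 were called (375; 844.4 by chance; DESeq2 7), with Cpz at 1.23 ± 0.30 and Pde7a at -1.06 ± 0.27 (adjusted p = 1), and in iWAT C3Hn 0 (1089; 0.588; DESeq2 40), with Zranb3 at 1.24 ± 0.35 and Cyp2f2 lower. Lists passed camera in all 4 tests at the preset correlation and in 0 with an estimated one.

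No difference in the size of the diet response over all genes between mitochondrial genomes passed the test. In eWAT it was 0.807 log2 units in C57n:C3Hmt and 0.695 in C57n:C57mt (difference 0.112, exact two-sided permutation p = 0.939, smallest possible 0.00041), and 0.741 in C3Hn:C57mt and 0.345 in C3Hn:C3Hmt (0.396, exact permutation p = 0.45, smallest possible 0.00082). In iWAT it was 0.621 and 0.724 in C57n:C3Hmt and C57n:C57mt (-0.103, exact permutation p = 0.728, smallest possible 0.0002), and 0.388 in C3Hn:C57mt against a negative estimate in C3Hn:C3Hmt (0.707, exact permutation p = 0.549, smallest possible 0.00071). Without single libraries the difference reached -0.332 in eWAT C57n, -0.127 in iWAT C3Hn and 0.219 in iWAT C57n.

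On chow, 0 genes were called between mtDNAs in eWAT of either nuclear background. In C57n (C57n:C3Hmt minus C57n:C57mt, 4 against 4) 2711 genes had unadjusted p under 0.05 (889.1 by chance; smallest adjusted p = 0.0793; DESeq2 540), with the smallest p at Pycrl, a proline synthesis enzyme (1.19 ± 0.22 log2 units), and Nsg1 (-1.06 ± 0.20). Both were called in 5 of the 8 fits without 1 library, and without C57n:C3Hmt chow replicate 3 edgeR called 327 genes. In C3Hn (4 against 3) there were 2223 (0.315; DESeq2 521), with Cd276 at 1.73 ± 0.37 and Ccng2 at -0.76 ± 0.16. OXPHOS genes there had a median of -0.42 (camera adjusted p = 1.24e-18, 0.372 with an estimated correlation). Epithelial RNA is in C3Hn:C57mt replicates 2 and 4 and in no C3Hn:C3Hmt chow library, and without the 6 libraries that carry it the median was -0.33 (2.54e-09, 0.735 with an estimated correlation). mt-Nd4 was not called in either (C3Hn -0.75, 0.375), nor were Cox2 and Atpase6.

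On HFD, 2 genes were called between mtDNAs in eWAT of C3Hn and 0 in C57n. Gnal, a stimulatory G protein subunit, was higher in C3Hn:C57mt than in C3Hn:C3Hmt by 3.67 ± 0.56 log2 units and thioredoxin reductase Txnrd1 by 1.21 ± 0.18 (3 against 4 libraries, each adjusted p = 0.00987; GC-corrected 3.34 ± 0.58, 0.0897, and 1.13 ± 0.22, 0.107). Each lost its call in 4 of 7 fits without 1 library (highest 0.279 for Gnal and 0.182 for Txnrd1), both without C3Hn:C3Hmt HFD replicate 1 or 3 or C3Hn:C57mt HFD replicate 3. With only the groups of this comparison in the fit neither was called (0.198 and 0.245). In the same comparison 2251 genes had unadjusted p under 0.05 and DESeq2 called 573; without the 6 eWAT libraries with epithelial RNA, of which 1 is C3Hn:C3Hmt HFD replicate 1, edgeR called 387, among them Adipoq (-1.78 ± 0.64, 0.257, then -1.91, 0.0206). OXPHOS genes had a median of -0.54 (camera adjusted p = 1.29e-19, 0.598 with an estimated correlation) and macrophage genes 0.84 (1.94e-06, 0.711 with an estimated correlation). The macrophage list mean was 6.94, 7.48 and 7.87 log2 CPM in C3Hn:C57mt and 5.02, 6.87, 7.19 and 6.32 in C3Hn:C3Hmt. In C57n 370 genes had unadjusted p under 0.05 (smallest adjusted p = 1; DESeq2 58), with Hexim1 at 0.64 ± 0.16 and the lysophosphatidic acid receptor Edg2 at -0.57 ± 0.17.

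In iWAT 0 genes were called between mtDNAs in all 4 comparisons. On chow, 154 genes in C57n (844.4 by chance; smallest adjusted p = 1; DESeq2 8) and 432 in C3Hn (1; DESeq2 9) had unadjusted p under 0.05, with Bpgm, an erythroid list gene, at 1.60 ± 0.46 log2 units in C57n and Fblim1 at -0.87 ± 0.26 in C3Hn. Bpgm ranged from 0.35 to 1.92 without single libraries, and C57n:C3Hmt chow replicate 3 had an erythroid list mean of 8.64 log2 CPM (others of its group 3.77 to 6.25). On HFD, 767 in C57n (0.143, DESeq2 10) and 1887 in C3Hn (0.119, DESeq2 37) had unadjusted p under 0.05. Lars2 (-2.74 ± 0.49) led in C57n and Cyp2e1 (-2.70 ± 0.48) in C3Hn. Ribosomal reads, whose bearing on Lars2 was not tested, were 0.43 to 0.77% in C57n:C3Hmt HFD and 0.95 to 8.64% in C57n:C57mt HFD. Cyp2e1 was called with the sequencing run as a covariate (0.0323). OXPHOS genes on HFD had a median of 0.33 in C57n (camera adjusted p = 3.96e-12, 0.858 with an estimated correlation) and interferon genes on chow 0.48 in C3Hn (1.14e-17, 0.15 with an estimated correlation). Mesothelial genes on chow in C57n (5 measured, 0 called, 1 lower adjusted over the list alone) had a median of -0.87 (6.92e-05, 0.0227 with an estimated correlation), the only list to pass both ways. mt-Nd4, Cox2 and Atpase6 were called in none of the 4.

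In gastrocnemius on chow (4 against 4) the mtDNA comparison called 0 genes in C57n (618 at unadjusted p under 0.05, 686.8 by chance; smallest adjusted p = 0.492; DESeq2 12) and 1 in C3Hn (1022; DESeq2 6), an unnamed gene model looked up after the values were seen (-5.06 ± 0.72 log2 units, 0.0349). That call was lost without C3Hn:C3Hmt replicate 1 or 3 or C3Hn:C57mt replicate 1, 2 or 3 (highest 0.252). The smallest p among named genes were those of the glycolytic Pfkl (0.45 ± 0.09, 0.492) and malic enzyme Me3 (-0.19 ± 0.05, 0.626) in C57n, and Myd116, a stress-induced phosphatase subunit (0.49 ± 0.11, 0.429), in C3Hn. mt-Nd4 was not called (0.11 in both backgrounds), nor were Cox2 and Atpase6. Immediate early genes in C57n had a median of -0.84 (camera adjusted p = 3.1e-10, 0.266 with an estimated correlation).

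Between the nuclear genomes 2680 genes were called in eWAT on chow (C57n minus C3Hn, 8 against 7 libraries), 1420 higher and 1260 lower in C57n. This count ranged from 1225 to 4340 without single libraries, and was 970 with only the chow groups in the fit. Trim12 was higher by 5.02 ± 0.34 log2 units (18.1 ± 2.42 against 0.563 ± 0.284 CPM; adjusted p = 2.94e-10) and Pttg1, securin, by 3.71 ± 0.28 (2.1e-09). Abhd1 was lower by 3.63 ± 0.22 (2.8e-11) and Hddc3 by 2.34 ± 0.19 (8.79e-09). H2-Ea, an MHC class II gene, had at most 2 counts in C57n, with 7 of 8 libraries at 0, against 123 ± 67.3 CPM in C3Hn, and like Rnaset2b (5.34 ± 0.40) shares reads with similar genes. Nnt (-0.18, 0.422) and Lep (-0.51, 0.474) were not called.

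Macrophage genes were lower in C57n eWAT: 13 of 28 fell and 0 rose (18 adjusted over the list alone, median -1.56 log2 units, camera adjusted p = 1.11e-07, 0.836 with an estimated correlation). Epithelial RNA is in 3 of the 8 C57n and 2 of the 7 C3Hn libraries. Without the 6 eWAT libraries with epithelial RNA 14 macrophage genes fell and 1 rose (median -1.28, camera adjusted p = 3.78e-07, 0.905 with an estimated correlation). Mmp12 was lower by 5.04 ± 0.76 (15.5 ± 8.87 against 564 ± 473 CPM; 8.74e-05), the lipid-sensing receptor Trem2 by 4.04 ± 0.67 (0.000265) and Itgax by 3.66 ± 0.62 (0.000316). Of 30 matrix genes 10 were lower and 0 higher (13 adjusted over the list alone, -0.66, camera adjusted p = 3.57e-06, 0.836 with an estimated correlation), with Mmp2 at -1.36 ± 0.26 (0.00116). Of 22 cholesterol synthesis genes 6 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.00712, 0.836 with an estimated correlation), with Fdft1, squalene synthase, higher (0.00198). Of 19 lipogenesis genes 3 were higher and 1 lower (5 and 1 adjusted over the list alone, 0.68, camera adjusted p = 0.0478, 0.836 with an estimated correlation, 0.0567 with RLE size factors), with Acly at 1.05 ± 0.26 (0.00996) and Thrsp at 1.98 ± 0.51 (0.0121, with only the chow groups in the fit 0.0881).

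In iWAT on chow 1978 genes differed between the nuclear genomes (8 against 8), 964 higher and 1014 lower in C57n. Rab6b was higher by 4.16 ± 0.22 log2 units (adjusted p = 8.47e-13), Trim12 by 5.64 ± 0.31 (1.66e-12) and the mitochondrial carrier Sfxn2 by 1.65 ± 0.10 (1.49e-11). Glyoxalase Glo1 was lower by 1.37 ± 0.08 (6.52e-12), and H2-Q2 by 7.06 ± 0.31, with reads shared among H2 genes. Of 19 lipogenesis genes 5 were higher and 0 lower (7 and 1 adjusted over the list alone, median 0.40, camera adjusted p = 0.0243, 0.92 with an estimated correlation), with Thrsp at 2.42 ± 0.37 (4.52e-05) and Acss2 at 1.68 ± 0.32 (0.00066). Of 28 macrophage genes 3 were higher and 8 lower (3 and 11 adjusted over the list alone, -0.33, camera adjusted p = 0.00751, 0.92 with an estimated correlation), with Mmp12 at -3.33 ± 0.43 (4.11e-06). The lymphocyte list means of these groups were 4.76 and 4.47 log2 CPM in the C57n lines and 1.99 and 3.65 in the C3Hn lines, and the macrophage list ran against the lymphocyte list on chow (Spearman -0.565, permutation p = 0.024, adjusted 0.036; n = 16). With lymphocyte and fast muscle covariates 2 macrophage genes were higher and 8 lower, with Mmp12 at -3.05 (5.96e-07).

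In gastrocnemius 4619 of 13735 genes differed between the nuclear genomes (8 against 8), 2353 higher and 2266 lower in C57n, 633 of them at least 2-fold. Pttg1 was higher by 5.20 ± 0.10 log2 units (adjusted p = 6.65e-16) and the netrin receptor Unc5a by 2.50 ± 0.07 (1.27e-13). Gpr179 had at most 1 count in C57n, with 6 of 8 libraries at 0, against 98.3 ± 10.2 CPM in C3Hn, at least 775-fold higher (9.82e-18). The alpha cardiac myosin heavy chain Myh6 was lower by 6.30 ± 0.15 (9.58e-15) and Hddc3, a hydrolase, was at -2.77 ± 0.05 (6.65e-16). Nnt was lower in C57n by 1.70 ± 0.07 (27.2 ± 3.79 against 88.3 ± 6.83 CPM), and mt-Nd4 higher by 0.34 ± 0.05 (3.84e-05), as were Cox2 (0.23 ± 0.05, 0.00236) and Atpase6 (0.25 ± 0.06, 0.00295). H2-Ea had 0 counts in all C57n libraries and was at least 30.8-fold higher in C3Hn.

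Of 73 OXPHOS genes in muscle 43 were lower and 1 higher in C57n (47 and 1 adjusted over the list alone, median -0.16 log2 units, camera adjusted p = 9.69e-08, 0.778 with an estimated correlation), with Atp5f1 at -0.49 ± 0.04 (1.81e-07). Of 18 TCA cycle genes 15 were lower and 1 higher (15 and 1 adjusted over the list alone, camera adjusted p = 0.00012, 0.695 with an estimated correlation), with Ogdh at -0.30 ± 0.04 (1.17e-05). Of 14 slow muscle genes 10 were lower and 1 higher (10 and 1 adjusted over the list alone, -0.58, camera adjusted p = 0.0105, 0.778 with an estimated correlation), with troponin Tnnt1 at -1.02 ± 0.18 (0.000342) and myosin light chain Myl2 at -0.91 ± 0.16 (0.000383). Of 25 interferon genes 14 were higher and 0 lower (14 adjusted over the list alone, 0.65, camera adjusted p = 0.00012, 0.695 with an estimated correlation), with the antiviral Rsad2 at 2.04 ± 0.32 (0.000105). The lymphocyte list mean was -0.58 to 0.11 log2 CPM in C57n muscle and -2.74 to -1.76 in C3Hn, and 4 of its 5 genes were higher (camera adjusted p = 0.00172, 0.173 with an estimated correlation).

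**Figure D3:**
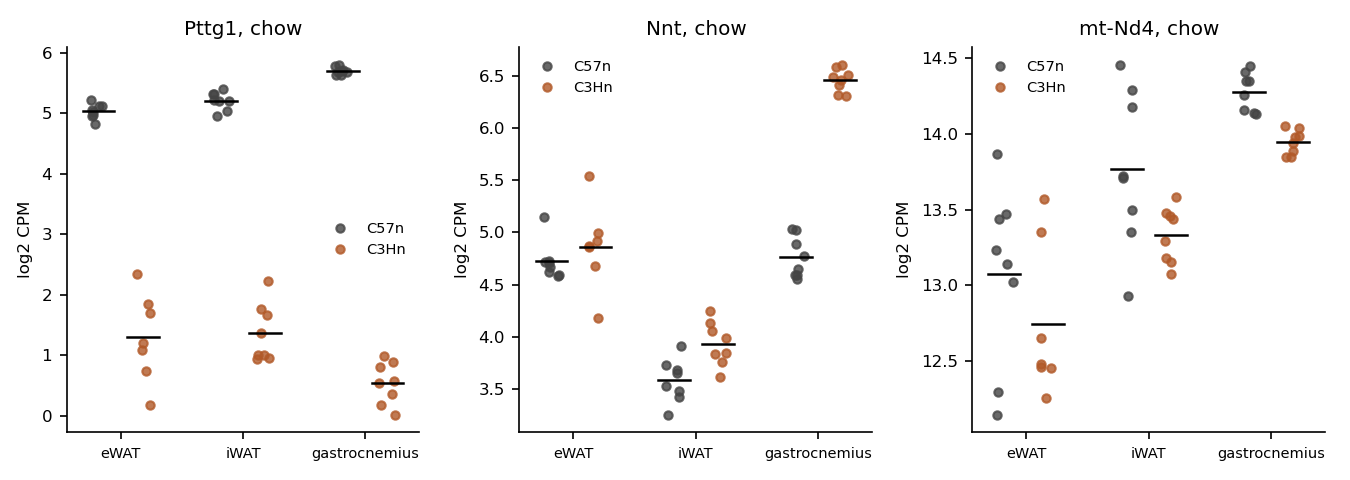
Expression (y axis, log2 CPM) of Pttg1, Nnt and mt-Nd4 on chow in 3 tissues (x axis), with points for libraries, grey for C57n and brown for C3Hn, and lines at means. Nnt differs in muscle (-1.70 log2 units) but is not called in eWAT (-0.18) or iWAT (-0.35).

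The diet response was also compared between nuclear genomes, a test chosen after the data were seen. In iWAT 121 genes were called, 38 higher and 83 lower in C57n than in C3Hn (4700 at unadjusted p under 0.05; 844.4 by chance; DESeq2 1454), from 9 without C3Hn:C57mt HFD replicate 1 to 2219 without C57n:C3Hmt chow replicate 1. Tcirg1, a proton pump subunit of lysosomes and osteoclasts, fell in C57n by 1.25 ± 0.15 log2 units and was at 0.29 ± 0.15 in C3Hn (difference -1.54 ± 0.21, adjusted p = 0.00217). The calcium-regulated Ras inhibitor Rasa4 (-1.02 in C57n, 0.07 in C3Hn, 0.0194) and the RNA editing enzyme Apobec1 (-0.13 and 0.76, difference -0.89 ± 0.16, 0.0212) were also lower in the difference, as was Plekhn1 (-2.55 ± 0.43, 0.0194). None of these 4 lost its call without 1 library. Higher in the difference were Cyp2e1 (0.57 in C57n, -1.74 in C3Hn, difference 2.32 ± 0.41, 0.0212), the sulfatase Arsk (0.61 ± 0.11, 0.023), Klf15 (1.35 ± 0.27, 0.0349) and Popdc2 (1.12 ± 0.22, 0.0349). They lost their call in 1, 11, 12 and 13 of 30 fits without 1 library (highest 0.0534, 0.0709, 0.0662 and 0.0718). The differences for Ucp1 (-5.35 ± 1.32, 0.0529) and Thrsp (2.02, 0.0616) were not called, but were with DESeq2 (0.00201 and 0.00707) and with lymphocyte and fast muscle covariates (-5.85, 0.0214, and 2.19, 0.0133). In eWAT 0 genes were called (3626; 889.1 by chance; DESeq2 1107).

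Removing the trend on GC content and length took the eWAT diet calls from 7294 to 4292 and the iWAT calls from 6345 to 2573. Of calls with a GC value 43.2% and 26.1% were kept; the others had a median absolute log2 fold change of 0.46 before and 0.17 after in eWAT, and of 0.42 and 0.14 in iWAT. G+C content of aligned reads was 49.5 ± 0.35% on chow and 48.9 ± 0.45% on HFD in eWAT (mean ± SD), and 49.0 ± 0.57% and 48.1 ± 0.57% in iWAT. Over 10 groups of genes ordered by GC content, the median log2 fold change went from 0.33 in the lowest to -0.48 in the highest in eWAT, and from 0.44 to -0.43 in iWAT. Of 576 values of named genes called before correction 415 stayed called, as did Mmp12 in eWAT and Ucp1 in iWAT, 153 were lost and 8 turned direction. Nuclear comparisons kept 76.4% of calls in eWAT, 90.1% in iWAT and 97% in muscle.

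**Figure D4:**
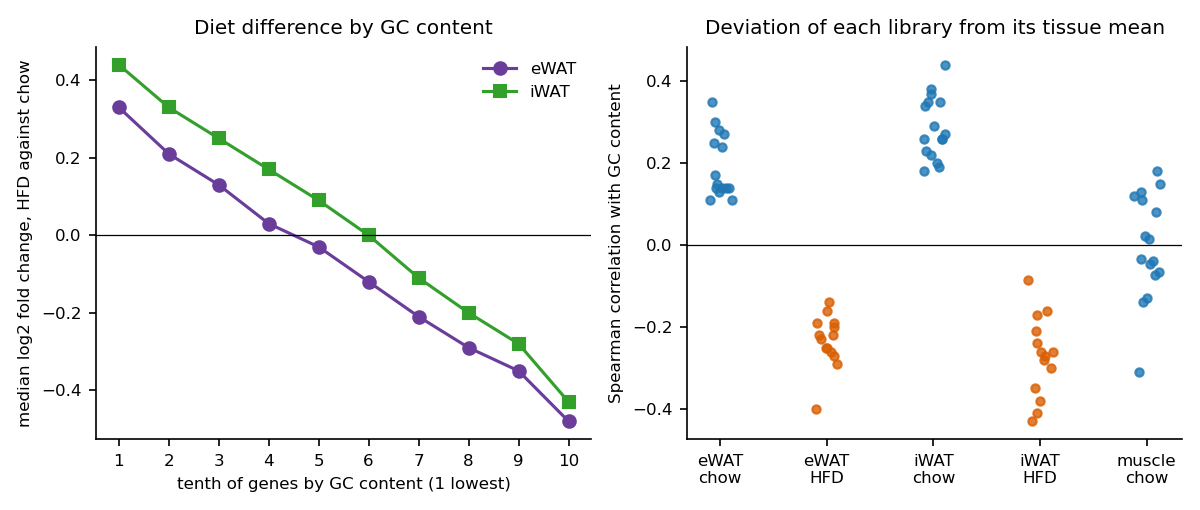
Left, median log2 fold change HFD against chow (y axis) by genes in 10 equal groups ordered by GC content (x axis) in eWAT (purple circles) and iWAT (green squares); right, Spearman correlation of each library's expression deviation with GC content (y axis) by tissue and diet, points being libraries. All chow fat libraries lie above 0 and all HFD fat libraries below 0.

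RNA of neighbouring tissue varied between libraries. In eWAT, 6 libraries carried epithelial RNA, among them C57n:C57mt chow replicate 3 (epididymis list mean 4.27 log2 CPM, others of its group -1.7 to -0.78) and C3Hn:C3Hmt HFD replicate 1 (8.01, others -3.24 to -2.66). In iWAT, lymphocyte genes followed Glycam1, a gene of lymph node venules, over 30 libraries (Pearson 0.98, Spearman 0.917, permutation p = 1e-05 for both, adjusted over 15 relations 7.5e-05 and 0.00015). Without the 2 farthest libraries these were 0.978 and 0.903, on chow 0.977 and 0.838 (n = 16), and on HFD 0.984 and 0.925 (n = 14).

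**Figure D5:**
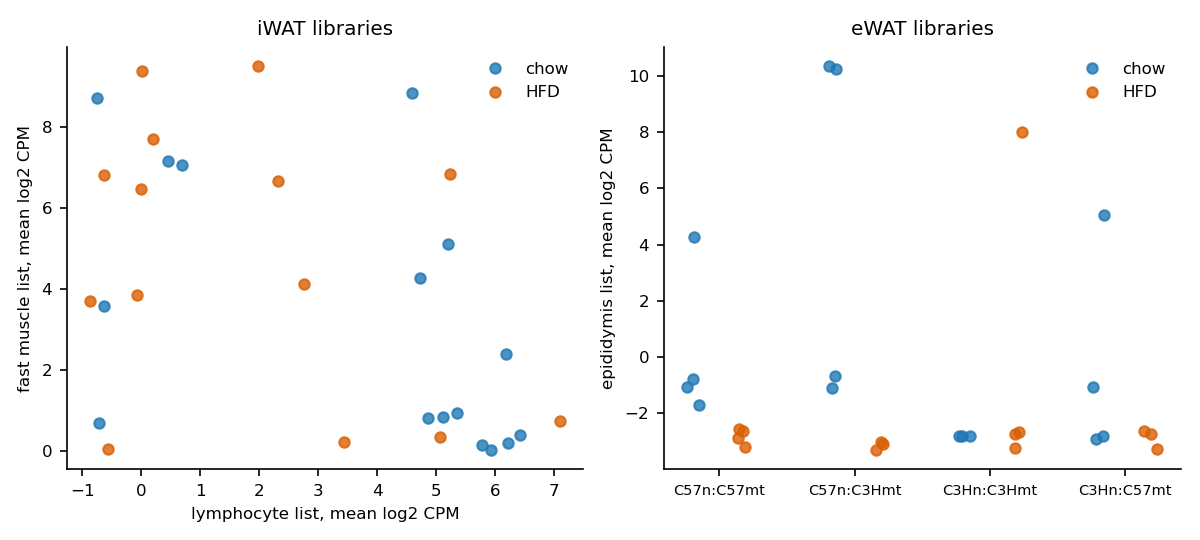
Left, mean log2 CPM of fast muscle genes (y axis) against lymphocyte genes (x axis) in iWAT libraries by diet; right, mean of epididymis genes (y axis) in eWAT libraries by genotype (x axis) and diet, points being libraries. C3Hn:C3Hmt HFD replicate 1 reaches 8.01 in eWAT.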

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

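The tests of neighbouring tissue and of the nuclear genome of each library in this part, and the diet by nuclear genome comparison, were chosen after the data were seen, and the tests of other groupings, library numbers and response size were written before.

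Diet calls in eWAT differ in number between genotypes, from 296 in C3Hn:C3Hmt to 3003 in C57n:C57mt. Unequal library numbers do not explain it alone, as with 3 per group mean calls still differed up to 8.57-fold. C57n:C57mt then no longer had the most. The values argue against epididymis RNA in C3Hn:C3Hmt HFD replicate 1 alone, since without that library the C3Hn:C3Hmt calls fell to 0.493 of their number. Without all 6 libraries with epithelial RNA they were 1814, against 2177 with it kept. The other 5, none in C3Hn:C3Hmt, stay open: they act there only through the joint fit, while C57n:C3Hmt went from 1241 to 365. Without HFD replicate 3, C3Hn:C3Hmt had 1568 calls. A larger response in the exchange line remains open (difference in C3Hn 0.396, exact permutation p = 0.45; 0.24 to 0.649 without single libraries).

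Diet calls may in part come from a difference in GC content between the runs. After each library's trend on GC content and length was removed 43.2% of calls in eWAT and 26.1% in iWAT were kept (GC content alone 44.4% and 26.1%, length alone 69.1% and 82.9%), and all chow fat libraries correlate positively with GC content while all HFD ones correlate negatively (eWAT chow 0.11 to 0.35, HFD -0.40 to -0.14). With length the correlation was above 0 in 4 of 15 chow and 12 of 14 HFD libraries in eWAT, and in 3 of 16 and 11 of 14 in iWAT. A difference between the HFD runs themselves gave 0 calls within groups, which does not bear on the chow run. Diet and run cannot be told apart here.

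Lymphocyte genes vary widely between iWAT libraries, which could come from lymph node in the tissue. Their mean follows the lymph node gene Glycam1 with a Spearman correlation of 0.917, while the erythroid list, as a measure of blood, follows it at 0.236. Blood as the reason needs both to rise alike, and the values argue against it, since the erythroid mean rose by 0.0671 per unit of the lymphocyte mean (95% bootstrap interval -0.0849 to 0.243).

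Other splits of the libraries tell whether chance can be excluded. For diet, no other split gave as many calls for the mean response in eWAT (7294 called, highest other split 42, 1 of 30 splits as large) and iWAT (6345 against 0, 1 of 30). The same held for C57n:C57mt in eWAT (3003 against 220, 1 of 35) and iWAT (2812 against 0, 1 of 35), and for C3Hn:C57mt in eWAT (1982 against 1031, 1 of 35) and iWAT (1300 against 308, 1 of 35). For C57n:C3Hmt in iWAT the real grouping gives the most calls (2790, 1 of 35), but another gives nearly as many (2723), and with only its own groups in the fit 0 genes were called. It cannot be excluded for eWAT C57n:C3Hmt (1241 against 2771, 5 of 35), eWAT C3Hn:C3Hmt (296 against 2865, 3 of 35) or iWAT C3Hn:C3Hmt (824 against 2445, 2 of 35 as large). The iWAT split with 2445 calls follows the lymphocyte list, with 3 libraries at 4.6, 4.73 and 7.1 against 4 at -0.87 to -0.56, which points to a structure of the samples. The eWAT split with 2771 calls is the diet grouping but for chow replicate 3, so it tells little about chance. The eWAT split with 2865 follows the correlation of expression with gene length (0.12 to 0.37 against -0.44 to -0.29), for reasons not tested.

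For mtDNA, chance cannot be excluded for eWAT on HFD in C3Hn (2 called, highest other split 144, 3 of 35 as large) or muscle in C3Hn (1 against 2, 5 of 35). Where 0 genes were called every split is as large by construction, so the count of splits decides nothing there. With 35 of 35 these are eWAT on chow in C57n (highest other split 6028) and C3Hn (477) and on HFD in C57n (3). Also with 35 of 35 are iWAT on chow in C57n (47) and C3Hn (1) and on HFD in C57n (44), and muscle in C57n (1). The diet by mtDNA interactions have 30 of 30 (2 and 1 in eWAT, 1 and 0 in iWAT). For iWAT on HFD in C3Hn (0 against 1, 10 of 10) there are too few splits. The eWAT chow split with 6028 calls put all 3 C57n libraries with epithelial RNA into the same group of 4, which points to a structure of the samples.

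For the nuclear genome, no other split gave as many calls in iWAT (1978 against 322, 1 of 30) or muscle (4619 against 1, 1 of 30). In eWAT chance stays open (2680 against 6263, 3 of 30 as large), and the larger split points to the libraries with epithelial RNA, 4 in the same group. Depot by diet splits (8 against 876, 6 of 30) part depots of 1 animal and decide nothing. Diet by nuclear genome splits mix nuclear genomes within groups and decide nothing (iWAT 121 against 4, 1 of 30, eWAT 0, 30 of 30).

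Of 151 groups and measures examined, all in groups of 4 libraries, 16 held a library far from the others of its group, with 7.6 to be found by chance. In eWAT, C57n:C3Hmt chow replicate 1 had a total of 25.61 M counts (others 27.34 to 27.54). Ucp1 was at 7.86 log2 CPM in C57n:C57mt chow replicate 3 (-2.94 to -1.1), and the epididymis list at 4.27 (-1.7 to -0.78). The epididymis list was at 8.01 in C3Hn:C3Hmt HFD replicate 1 (-3.24 to -2.66), the keratinocyte list at 3.43 (-1.9 to -1.51) and the fast muscle list at 0.23 (-0.02 to 0.01). In C3Hn:C57mt chow replicate 2 the lymphocyte list was at 1.28 (-0.48 to -0.26) and the fast muscle list at 4.11 (0.21 to 0.24). The accessory gland genes Sbp and Pbsn, looked up outside these measures, were at 14.39 (1.69 to 1.87) and 12.23 (-0.86 to -0.46) there, and without this library the eWAT nuclear calls went from 2680 to 4340.

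In iWAT, C3Hn:C57mt chow replicate 2 had the lymphocyte list at -0.76 (4.87 to 5.36) and the fast muscle list at 8.71 (0.8 to 0.93). C57n:C3Hmt chow replicate 1 had them at 0.46 (5.94 to 6.42) and 7.16 (0.02 to 0.39). The lymphocyte list was at 3.44 in C57n:C57mt HFD replicate 1 (-0.07 to 0.2), the keratinocyte list at 0.17 in C3Hn:C3Hmt chow replicate 2 (-1.6 to -1.37), and Ddx3y at 3.19 in C57n:C3Hmt HFD replicate 1 (6.36 to 6.95). In muscle Ddx3y was at 3.29 in C57n:C57mt chow replicate 1 (4.2 to 4.34). Groups of 3 were not examined in this way. Of these, iWAT C3Hn:C3Hmt HFD replicate 3 had the lymphocyte list at 7.1 (others -0.87 and -0.56), Ddx3y at 3.24 (6.33 and 6.4) and Pttg1 at 4.55 (0.72 and 1.01), and it is the only library of its run. Without it the depot by diet calls went from 8 to 586 and the diet calls of its group from 824 to 279. Its nuclear genome follows its label by 92 genes higher and 74 lower in C57n on chow in all 3 tissues (mean difference -2.64, C3Hn libraries on HFD up to -2.64 and C57n libraries on HFD from 2.25), and its other values were not explained. Genes whose diet response differs numbered 8 between depots and 121 between nuclear genomes in iWAT.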

How the results depend on the processing

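Which choices were made after the data were seen: the fits without all 6 or 5 eWAT libraries with epithelial RNA, the lymphocyte and fast muscle covariates, the 11 list members under older symbols, the reading of Cox2 and Atpase6 as mtDNA-encoded genes, the removal of the GC content and length trend together or alone, and every diet by nuclear genome result. The main limits are that diet and sequencing run are the same split, that groups hold 3 or 4 animals, that neighbouring tissue enters some libraries, and that all but 1 of the list tests pass only at the preset correlation. RLE size factors changed none of 54 results beyond 1.5-fold, and adding 11 list members under older symbols changed none of 20 list results so. For results that moved, the cause was not tested except where stated.

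DESeq2 gave more calls in 22 of 30 results. For the diet response it called 1391 genes in eWAT C3Hn:C3Hmt (edgeR 296), 3639 in C3Hn:C57mt (1982) and 3426 in C57n:C3Hmt (1241), and in iWAT 1772 in C3Hn:C3Hmt (824) and 2016 in C3Hn:C57mt (1300). It called 652 genes for the depot by diet interaction (8). For the diet by mtDNA interactions it called 387 in eWAT C3Hn, 66 in eWAT C57n, 40 in iWAT C3Hn and 7 in iWAT C57n (all 0 with edgeR). For mtDNA in C3Hn and C57n it called 573 (2) and 58 in eWAT on HFD and 521 and 540 on chow. In iWAT these were 37 and 10 on HFD and 9 and 8 on chow, and in muscle 6 (1) and 12 (0). For diet by nuclear genome it called 1107 in eWAT (0) and 1454 in iWAT (121). On counts simulated for the mean diet comparison in eWAT 21% of its calls were false, against 2.4% with edgeR. DESeq2 was not run on the simulated counts of other comparisons.

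Removing the GC content and length trend gave 4292 genes for the mean diet response in eWAT (from 7294) and 2573 in iWAT (from 6345). With GC content alone these were 4235 and 2453, and with length alone 6047 and 6093. Within genotypes it gave 1190 in eWAT C57n:C57mt, 0 in C57n:C3Hmt, 2 in C3Hn:C3Hmt and 210 in C3Hn:C57mt, and in iWAT 466, 432, 6 and 26. It gave 0 genes for the depot by diet interaction and 0 for mtDNA on HFD in eWAT C3Hn. Lists passing camera were 11 for muscle mtDNA in C3Hn (from 6), 9 for iWAT mtDNA on HFD in C57n (from 14) and 11 for the iWAT nuclear comparison (from 7).

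Without any expression filter there were 5 genes for the depot by diet interaction, 170 for diet in eWAT C3Hn:C3Hmt, 786 in eWAT C57n:C3Hmt, 548 in iWAT C3Hn:C3Hmt and 46 for diet by nuclear genome in iWAT. Thinned to the smallest library, muscle mtDNA in C3Hn had 0 genes. With limma-voom the depot by diet interaction had 5 genes, and 31 with the animal as a block.

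With the HFD run as a covariate the eWAT mean diet response had 2884 genes, C3Hn:C3Hmt 101, C3Hn:C57mt 992 and C57n:C3Hmt (HFD in 1 run) 0. In iWAT C3Hn:C3Hmt had 169, diet by nuclear genome 43 and mtDNA on HFD in C3Hn 2.

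With only the groups of a comparison in the fit, diet in eWAT called 0 genes in C3Hn:C3Hmt, 0 in C57n:C3Hmt and 1448 in C57n:C57mt, and in iWAT 0 in C3Hn:C3Hmt, 2571 in C3Hn:C57mt, 0 in C57n:C3Hmt and 5077 in C57n:C57mt. The nuclear comparison called 970 in eWAT and 2979 in iWAT, and mtDNA 0 in eWAT C3Hn on HFD and 0 in muscle C3Hn.

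With 3 libraries per group (mean of 10 draws) diet called 191.8 genes in eWAT C3Hn:C3Hmt, 1193.5 in eWAT C57n:C57mt, 198.4 in iWAT C3Hn:C3Hmt, 641.6 in iWAT C3Hn:C57mt, 1392.6 in iWAT C57n:C3Hmt and 782.2 in iWAT C57n:C57mt.

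With lymphocyte and fast muscle covariates, chosen after the data were seen, diet in iWAT called 2379 genes in C3Hn:C3Hmt and 2196 in C3Hn:C57mt, diet by nuclear genome 1905, and 7 lists passed for mtDNA on chow in C57n (from 13).

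Without the 6 eWAT libraries with epithelial RNA, diet called 1814 genes in eWAT C3Hn:C3Hmt, 3070 in C3Hn:C57mt and 459 in C57n:C3Hmt, and the depot by diet interaction 43. The diet by mtDNA interaction in C57n called 1, diet by nuclear genome in eWAT 1, mtDNA on HFD in C3Hn 387 and mtDNA on chow in C57n 24. The difference in response size in eWAT C57n turned to -0.074. With C3Hn:C3Hmt HFD replicate 1 kept and the other 5 left out, diet called 2177 in eWAT C3Hn:C3Hmt and 365 in C57n:C3Hmt. Lists passing without the 6 were 15 for the eWAT mean diet response (from 8), 15 for mtDNA on chow in C3Hn (from 23) and 9 for the nuclear comparison (from 17).

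With the correlation between genes estimated in camera, 1 list (mesothelial) passed for iWAT mtDNA on chow in C57n (from 13) and 0 for each of the other 19 comparisons tested: depot by diet (from 14), eWAT diet mean (8), eWAT diet by mtDNA in C3Hn (15) and C57n (13), eWAT mtDNA on HFD in C3Hn (16) and C57n (12) and on chow in C3Hn (23) and C57n (15), eWAT nuclear (17), muscle mtDNA in C3Hn (6) and C57n (17), muscle nuclear (10), iWAT diet mean (12), iWAT diet by mtDNA in C3Hn (19) and C57n (13), iWAT mtDNA on HFD in C3Hn (12) and C57n (14) and on chow in C3Hn (17), and iWAT nuclear (7).

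Leaving out each library in turn, the mean diet response stayed between 6498 (without C3Hn:C57mt HFD replicate 3) and 7699 genes in eWAT. Diet in eWAT C3Hn:C3Hmt ranged from 5 (without its chow replicate 3) to 1568 (HFD replicate 3), C3Hn:C57mt from 409 (HFD replicate 3) to 2113 (chow replicate 1), C57n:C3Hmt from 50 (HFD replicate 1) to 2590 (chow replicate 3) and C57n:C57mt from 844 (chow replicate 3) to 3161 (chow replicate 2). In iWAT C3Hn:C3Hmt ranged from 279 (HFD replicate 3) to 2354 (HFD replicate 1), C3Hn:C57mt from 497 (HFD replicate 2) to 1287 (chow replicate 2), C57n:C3Hmt from 1396 (chow replicate 2) to 4138 (chow replicate 1) and C57n:C57mt from 1452 (chow replicate 1) to 3180 (chow replicate 2). The eWAT nuclear comparison ranged from 1225 (C3Hn:C3Hmt chow replicate 2) to 4340 (C3Hn:C57mt chow replicate 2), and the depot by diet interaction from 3 (eWAT C57n:C3Hmt chow replicate 4) to 586 (iWAT C3Hn:C3Hmt HFD replicate 3).

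Leaving out libraries moved mtDNA results as follows. In eWAT, mtDNA on HFD in C3Hn ranged from 0 (without C3Hn:C3Hmt HFD replicate 1) to 149 (C3Hn:C3Hmt HFD replicate 2), on HFD in C57n from 0 to 1 (C57n:C3Hmt HFD replicate 3) and on chow in C57n from 0 to 327 (C57n:C3Hmt chow replicate 3). The interactions ranged from 0 to 1 in C3Hn (C3Hn:C57mt HFD replicate 1) and in C57n (C57n:C3Hmt HFD replicate 3). In iWAT, mtDNA on HFD ranged from 0 to 2 in C3Hn (C3Hn:C3Hmt HFD replicate 1) and from 0 to 7 in C57n (C57n:C57mt HFD replicate 1), and muscle mtDNA in C3Hn from 0 (C3Hn:C3Hmt replicate 1) to 2 (C3Hn:C3Hmt replicate 4). Diet by nuclear genome ranged from 0 to 7.1e+02 in eWAT (C3Hn:C3Hmt HFD replicate 3) and ranged from 9 (C3Hn:C57mt HFD replicate 1) to 2219 (C57n:C3Hmt chow replicate 1) in iWAT. Response size differences ranged from 0.24 (C3Hn:C3Hmt HFD replicate 3) to 0.649 (C3Hn:C3Hmt chow replicate 3) in eWAT C3Hn, from -0.332 (C57n:C3Hmt chow replicate 4) to 0.385 (C57n:C3Hmt chow replicate 3) in eWAT C57n, from -0.127 (C3Hn:C3Hmt HFD replicate 3) to 1.034 (C3Hn:C57mt HFD replicate 2) in iWAT C3Hn, and from -0.303 (C57n:C57mt chow replicate 2) to 0.219 (C57n:C3Hmt chow replicate 1) in iWAT C57n.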

Other observations

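All observations here were chosen after the data were seen, and none was tested beyond the values given.

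Gene counts of Ccl21a, a lymph node chemokine, were 0 in all C3Hn chow libraries of both fat depots, so that C57n is at least 185-fold higher in eWAT and at least 109-fold higher in iWAT, and reads shared with copies of this gene make it uncertain.

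The correlation between the depots of the same animal, over genes after group means are removed, had a median of 0.11 over 20 animals, and 0.029 for eWAT with muscle over 7 animals and 0.053 for iWAT with muscle over 10.

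The accessory gland gene Sbp was at 14.39 log2 CPM in eWAT C3Hn:C57mt chow replicate 2, at 1.5 to 2.21 in the other 7 eWAT libraries of its lane, which include 1 of C57n, and at -3.44 to -2.97 in the 7 of the other lane.

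The liver gene Alb reached 9.54 log2 CPM in iWAT C3Hn:C3Hmt HFD replicate 2 and 9.53 in iWAT C3Hn:C57mt chow replicate 3, and Apoa1 6.59 and 7.19.

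The share of Nnt reads given to its first transcript was 28.4 ± 7.43% (mean ± SD) in C57n and 22.3 ± 7.15% in C3Hn libraries.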
